A study of Mus musculus with 20 samples.

How the data were processed

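RNA of mouse bone marrow-derived macrophages was taken up in TRIzol, labelled as biotinylated cRNA and hybridised to Illumina mouse BeadChips, 20 arrays in 4 groups of 5 on 6 chips. Cells were cultured for 6 days with 40 ng/ml M-CSF and 10 percent fetal calf serum. Groups, doses and hours were taken from the labels. How long untreated or crystal-only cells stood beside the 6 h of cyclodextrin is not given in the sources used here.

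One deposited file holds, per the file headers and the values, an average bead signal (intensity, linear scale, not background-subtracted) for each of 45281 probes and 20 arrays. The same deposited file holds a detection p-value for each probe and array, per the file headers, which compares the probe with negative control beads. The authors' value table is in log2 units. Its scale and centring were found by recomputing it: log2 of the bead signals, quantile normalised over the 20 arrays, then adjusted so that each of 5 sets of 4 arrays, 1 of each group, had the same mean for every probe. The recomputed table differed from it with an SD of 0.00105 and by at most 0.0173, and all 20 arrays matched their own column best. Column medians of the authors' table were 6.71 to 6.72. Partek is the tool per the submitters' processing notes, with no version or steps stated.

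Values reported here came from the bead signals. In R 4.3.3 with limma 3.58.1, neqc subtracted background by a normal-exponential model with controls inferred from the detection p, added an offset of 16, quantile normalised and took log2. The offset shrinks the fold changes of dim probes, so a change from near background is an underestimate. Probes detected at p below 0.05 on at least 5 arrays were kept, which left 18348. Of all probes, 34885 had 1 gene symbol in the annotation, 18 had several and 10378 had none. Probes with several symbols or none were not used. Of the 15671 detected probes with 1 symbol, the probe with the highest mean over all arrays stood for its gene, giving 10018 genes. Of 106 calls of named genes with further detected probes, 2 had a probe of opposite sign, and the size of a change could differ between probes. Median bead signal was 105 across arrays (86.6 to 128), and the 75th percentile lay between 107 and 192.

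A linear model of the 4 groups was fitted per gene with limma (lmFit, contrasts.fit, eBayes), two-sided, for 5 comparisons of groups and the interaction of crystals and cyclodextrin. Genes with a Benjamini-Hochberg adjusted p below 0.05 over all genes tested were called. A value after ± is a standard error (SE) from this model unless named as SD or as coming from the set-block fit. Where no array of the lower group detected a gene, its fold is a lower bound, taken against the lowest detected signal of each of those arrays.

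A total of 30 gene lists, 20 of pathways and 10 of cell types, was fixed before the data were examined, as were the groups, the filter, the tests, the rule for named genes and all alternatives except those named below as added. They hold 508 genes, of which 467 had a named probe and 350 were tested. The 24 lists with at least 5 measured genes were tested with camera (preset correlation 0.01, two-sided), adjusted over the lists of a contrast, and beside it with an estimated correlation and with fry. Lists of neutrophil, dendritic, osteoclast, T and NK, erythroid and mast cell markers had too few measured genes and were not tested. Without a block, no call was made in any contrast for the lists of endoplasmic reticulum chaperones, lipid droplet and PPAR genes, alternative activation, glycolysis and hypoxia, complement, mitochondrial respiratory chain, actin cytoskeleton, monocytes, stromal fibroblasts and B cells.

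Named genes were the 6 with the largest rise and the 6 with the largest fall among those called in a comparison (clones without a gene name passed over), up to 4 members of each described list with the largest change, and 23 genes of sterol handling and inflammation whatever their result. Some of those 23 were not analysed here, and Il6 and Arg1 did not pass the detection filter.

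Alternatives set in advance were quantile normalization without background correction, scale normalization, the authors' table, no or a stricter detection filter, all detected probes, array weights, trend and robust fitting, the chip as a fixed or random block, the replicate number as a block, only the groups of a contrast, an added minimum fold, and leaving out each array. Chosen after seeing the data were the set of arrays as a block (alone and with the authors' table), chips 1 and 5 or chips 2, 3, 4 and 6 alone, and leaving out the 3 arrays of lowest signal. The model was tested on simulated data with 50 changed genes of each size in the layout of both treatments against crystals. It recovered 88 percent of changes of log2 1 without the set block and 98 percent with it (34 and 54 percent at log2 0.5). False calls were 5 of 166 without the block and 10 of 186 with it. Each simulated change was equal on all arrays of its group, genes varied independently, and each fit had its own simulated data. Effects that differ between chip batches were not simulated, so these shares do not give the power of the real comparison.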

Results

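Gene expression was measured on 20 Illumina mouse BeadChip arrays of bone marrow-derived macrophages from C57BL/6 mice, cells grown from marrow for 6 days in M-CSF, the growth factor that drives macrophage formation. The arrays fell into 4 groups of 5. These were untreated cells, cells given cholesterol crystals for 3 h (200 ug, a dose the labels give relative to cell number), cells given 10 mM hydroxypropyl-beta-cyclodextrin for 6 h, and cells given the crystals and then the cyclodextrin. Cyclodextrin is a ring of sugars that binds cholesterol in its core. Median bead signal per array lay between 86.6 and 128, and 15342 to 17892 of 45281 probes per array were detected, or 33.9 to 39.5 percent. After filtering, 10018 genes were tested, and the number of arrays limits the precision of every value below. The labels do not state whether replicates were separate animals or cultures, so each p-value measures the spread between these arrays, some of which could be technical.

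A pair of structures in the arrays bear on every comparison. The untreated cells carry an age label of 10 to 15 months and the other 3 groups one of 2 to 5 months, so the labelled age and the treatment cannot be told apart where untreated cells enter. The age label was taken as given, and the values cannot show whether it is right. How long untreated and crystal-only cells stood is not given either. A difference in time thus cannot be told apart from the treatment where these cells are compared with others. The arrays also fell into 5 sets of 4 arrays, 1 of each group, which were found in the authors' values and used as a block in an alternative chosen after seeing the data. Sets 1 to 3, on chips 1 and 5, had high Xist (up to 11.5 on the log2 scale) and low Eif2s3y, the pattern of female cells. Sets 4 and 5, on chips 2, 3, 4 and 6, had low Xist (4.26 to 4.45) and high Eif2s3y, the pattern of male cells, so the inferred sex and the chip batch coincide. The study concerns liver X receptors, the LXR sterol sensors, and its design text mentions mice lacking them, but the labels give no genotype. Nr1h3, which encodes LXR alpha, lay between 9.32 and 11.40 (log2) on all 20 arrays, and no array was assigned a genotype.

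The first comparison, crystals against untreated cells, asks what cholesterol crystals did to macrophages. In crystal-loaded cells 14 of 18 amino acid stress genes rose, 12 of 18 genes for making or taking up cholesterol fell, and 3 of 12 LXR targets rose (n = 5 per group here and in every comparison of groups below). Abcg1, the transporter that passes cholesterol to lipoprotein particles, rose 7.89-fold (log2 2.98 ± 0.235 SE, adjusted p = 1.97e-07). Cyp51, a demethylase of cholesterol synthesis, was 4.28-fold lower (log2 -2.10 ± 0.184, adjusted p = 7.54e-07), and Ddit3, the stress transcription factor CHOP, rose 7.46-fold (log2 2.90 ± 0.208, adjusted p = 5.32e-08). Each of these 3 genes moved the same way in 5 of 5 sets. In all, 851 genes rose and 899 fell, of which 231 and 141 changed at least 2-fold.

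Cholesterol synthesis and uptake genes of SREBP-2, the transcription factor that is activated when sterol is low, fell as a group after crystals. Of 18 measured, 0 rose, 12 fell and 6 did not pass, and 14 fell adjusted over the list alone. The list median was -0.79 log2 (camera adjusted p = 1.57e-13, and adjusted p = 0.0114 with an estimated correlation), with -0.98 on chips 1 and 5 and -0.61 on the other chips. The sterol carrier Stard4 was 4.36-fold lower, Fdps, a synthase of the pathway's isoprenoid part, 3.07-fold lower, and Insig1, the sterol-regulated brake on SREBP processing, 2.21-fold lower. Of 12 LXR targets of cholesterol efflux and lipoprotein metabolism, 3 rose, 0 fell and 9 did not pass (4 rose adjusted over the list alone). Their median was 0.19 (camera adjusted p = 0.0122, lost at adjusted p = 0.129 with an estimated correlation). The risers were Abcg1, the efflux transporter Abca1 (log2 0.90 ± 0.162, at least 1.48-fold higher, since no untreated array detected it) and Mylip, a ubiquitin ligase (at least 1.31-fold higher). Fatty acid synthesis genes of SREBP-1 split, with 4 of 12 higher, such as Scd1 (3.03-fold), and 3 lower, such as Elovl6 (log2 -1.09). Srebf1, the gene of SREBP-1 and itself an LXR target, rose 1.72-fold (adjusted p = 0.0102), while Apoe did not pass (log2 -0.08).

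Stress genes were the other large group to rise with crystals. Among 18 genes of the ATF4 amino acid stress response, 14 rose and 0 fell (15 rose adjusted over the list alone), with a median of 1.17 (camera adjusted p = 7.60e-14, and adjusted p = 0.0493 with an estimated correlation). Slc7a11, the cystine importer, rose 10.0-fold, the pseudokinase Trib3 9.51-fold and the glutathione-degrading enzyme Chac1 7.41-fold. Of 15 NRF2 oxidative stress genes, 6 rose and 0 fell (8 adjusted over the list alone), among them Gsta3 (7.92-fold), a glutathione transferase, and Hmox1 (3.16-fold), which breaks down heme. Other probes gave a smaller change for Gsta3 (log2 0.46 against 2.99), Slc7a11 (0.74 to 2.41 against 3.33), Trib3 (as low as 1.59 against 3.25) and the proton pump subunit Atp6v1h (0.33 against 1.14). Their median was 0.45 (camera adjusted p = 7.35e-06, lost at adjusted p = 0.138 with an estimated correlation). Heat shock and metallothionein genes gave 5 of 12 higher, led by the chaperone Hspa1a (6.93-fold). That list's median was 0.42 (camera adjusted p = 0.0098, lost at adjusted p = 0.232 with an estimated correlation). Of 24 lysosome and autophagy genes of TFEB, 8 rose, such as Atp6v1h (2.20-fold) and the autophagy receptor Sqstm1 (2.43-fold), and 1 fell (Uvrag). Their median was 0.19 (camera adjusted p = 5.05e-04, and adjusted p = 0.0493 with an estimated correlation).

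Some genes of growth and macrophage identity fell with crystals. Of 18 cell cycle genes, 0 rose and 7 fell (13 adjusted over the list alone), such as the nucleotide reductase subunit Rrm2 (log2 -0.74) and cyclin Ccnd1 (log2 -0.74). Their median was -0.49 (camera adjusted p = 2.19e-05, lost at adjusted p = 0.129 with an estimated correlation). Of 12 macrophage markers, 0 rose and 4 fell, among them the chemokine receptor Cx3cr1 (4.49-fold lower) and the endotoxin co-receptor Cd14 (2.20-fold lower). The marker list's median was -0.45 (camera adjusted p = 0.0253, lost at adjusted p = 0.365 with an estimated correlation). The anti-inflammatory cytokine Il10 was 2.53-fold lower and the interleukin-1 receptor antagonist Il1rn 5.45-fold higher. The growth factor receptor Kit rose 15.6-fold from a level that only 2 of 5 untreated arrays detected, and the poly(A) polymerase Tent5c rose 12.1-fold. Of the inflammatory genes, Tnf (log2 1.02, adjusted p = 0.337), Nlrp3 (log2 0.01, adjusted p = 0.992) and Ccl2 (log2 0.68, adjusted p = 0.201) did not pass without a block. Neither did the 17 NF-kB mediators as a list without a block (median 0.48, camera adjusted p = 0.0766), of which Tnfaip3 alone rose. The list was called with the chip as a block (median 0.57, camera adjusted p = 0.00550) and with the set as a block (camera adjusted p = 0.0297). Il1b, the gene of interleukin-1 beta, differed between chip batches before treatment, with a mean of 9.23 in untreated cells on chips 1 and 5 and 5.41 on the others (log2). After crystals its change was log2 -3.45 on chips 1 and 5 and 0.97 on the others (adjusted p of the difference 1.88e-04), and it was not called overall (log2 -1.68, adjusted p = 0.246).

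After crystals, 1254 genes rose and 1518 fell with the set as a block. The counts were 1277 and 1551 on chips 1 and 5 alone and 257 and 172 on the other chips. With the chip as a block they were 786 and 892. Chips 1 and 5 held 3 arrays per group and the other chips 2, so the batch counts here and below also differ in power. Some called genes rose more on chips 1 and 5 than on the others, by a test of the difference, such as Tent5c (log2 4.44 and 2.32, adjusted p of the difference 1.88e-04), Slc7a11 (4.18 and 2.04), Gsta3 (3.68 and 1.95), Chac1 (3.42 and 2.10), Kit (4.55 and 3.09) and Hspa1a (3.96 and 1.03). Scale in place of quantile normalization moved the balance to 423 higher and 230 lower.

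**Figure D1:**
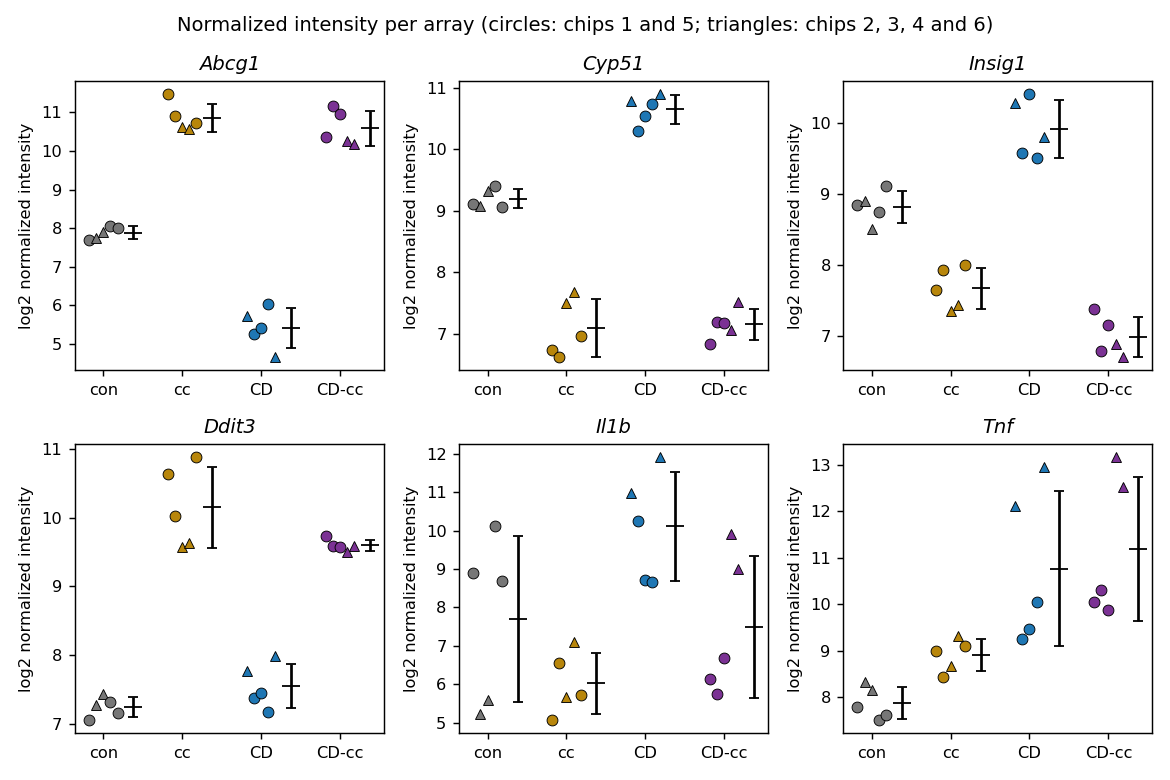
Normalised intensity (log2, y axis) of 6 genes on each of the 20 arrays, by group (x axis: con, untreated; cc, crystals; CD, cyclodextrin; CD-cc, crystals then cyclodextrin), with circles for chips 1 and 5, triangles for chips 2, 3, 4 and 6, and horizontal bars with whiskers for the group mean and SD (n = 5). Abcg1 averaged 7.88 in untreated cells, 10.86 with crystals, 5.42 with cyclodextrin and 10.59 with both, and Cyp51 lay highest with cyclodextrin alone (10.65). In both groups given cyclodextrin, Il1b and Tnf lay higher on chips 2, 3, 4 and 6, while with crystals alone the batches overlapped. In untreated cells Il1b lay higher on chips 1 and 5.

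Cyclodextrin against untreated cells asks what the sugar did in the absence of added crystals. Genes for making cholesterol and for NF-kB-driven inflammation rose, and Abcg1 was 5.51-fold lower (log2 -2.46 ± 0.235, adjusted p = 8.14e-06). Mvd, the decarboxylase of the mevalonate pathway, rose 3.47-fold (log2 1.80 ± 0.201, adjusted p = 7.38e-05), and Sqle, which makes the first oxygenated sterol precursor, rose 2.45-fold (log2 1.29 ± 0.168, adjusted p = 4.59e-04). Tnf rose 7.41-fold (log2 2.89 ± 0.665, adjusted p = 0.0369) and Acod1, the enzyme that makes itaconate, 15.0-fold (log2 3.91 ± 0.686, adjusted p = 0.00653). The change of Acod1 was log2 2.38 on chips 1 and 5 and 6.19 on the others (adjusted p of the difference 1.49e-05). Abcg1, Mvd, Tnf and Acod1 each moved one way in 5 of 5 sets. In all, 85 genes rose and 28 fell, 48 and 10 of them by at least 2-fold.

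Most SREBP-2 genes rose after cyclodextrin. Of 18, 13 rose, 0 fell and 5 did not pass, and 16 rose adjusted over the list alone, with a median of 0.98 (camera adjusted p = 1.14e-32, and adjusted p = 8.29e-05 with an estimated correlation). That median was 0.94 on chips 1 and 5 and 1.17 on the others. Fdps rose 2.78-fold and Insig1 2.14-fold. Of the 12 SREBP-1 genes the elongase Elovl6 passed (2.35-fold higher), and 2 passed with the set block, with a list median of 0.37 (camera adjusted p = 4.82e-06, and adjusted p = 0.00105 with an estimated correlation). LXR targets were not called as a list (median -0.02, camera adjusted p = 0.0952). None rose and 2 of 12 fell without a block, Abcg1 and Mertk, a receptor for dying cells (2.72-fold lower). Nr1h3 rose with the set as a block (log2 0.77, higher in 5 of 5 sets, set-block adjusted p = 0.0152, adjusted p = 0.202 without it). Its other probe gave log2 0.25. Abca1 was detected on no array of either group, so no change in it could be measured.

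Of 17 NF-kB inflammatory mediators, 7 rose, 0 fell and 10 did not pass, and 12 rose adjusted over the list alone. Examples are the chemokines Cxcl10 (6.63-fold) and Ccl3 (6.12-fold) and the co-stimulatory receptor Cd40 (6.12-fold), though another probe of Cxcl10 gave log2 1.06 and the lowest of Cd40 log2 0.29. The list median was 1.84 (camera adjusted p = 1.20e-20, and adjusted p = 0.0438 with an estimated correlation, which became 0.0729 with the set block). It was 0.90 on chips 1 and 5 and 2.79 on the other chips, a difference with a camera adjusted p of 6.68e-28 (adjusted p = 5.50e-04 with an estimated correlation). On chips 1 and 5 and on the others, Tnf rose by log2 1.95 and 4.30, Cxcl10 by 1.69 and 4.29, Ccl3 by 1.93 and 3.64 and Cd40 by 1.85 and 3.76. Il1b changed by log2 -0.02 on chips 1 and 5 and 6.05 on the others (adjusted p of the difference 1.58e-06), from 9.23 to 9.21 and from 5.41 to 11.46, so most of that gap lay in the untreated cells. It was not called overall (log2 2.41 ± 0.937, adjusted p = 0.312).

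Smaller list shifts after cyclodextrin did not hold with an estimated correlation. Interferon-stimulated genes had a median of 0.42 (camera adjusted p = 4.77e-06, adjusted p = 0.457 with an estimated correlation), with 0 of 19 past the test without a block and 5 higher with the set block, such as Rsad2 (log2 1.38, set-block adjusted p = 0.0165, with 0.60 on chips 1 and 5, not called there, and 2.54 on the others). ATF4 genes had a median of 0.25 (camera adjusted p = 0.00654, adjusted p = 0.561 with an estimated correlation), with 0 of 18 past it without the block and 1 with it. For inflammasome and interleukin-1 genes the median was 0.16 (camera adjusted p = 0.0373, adjusted p = 0.368 with an estimated correlation), and 1 of 14 rose (2 with the set block), Casp4, an inflammatory caspase (2.50-fold, log2 1.32, while its other probes gave 0.20 and 1.09). Vegfa, the vascular growth factor, was 3.37-fold lower (log2 -1.75 ± 0.334, adjusted p = 0.0119). Cytip, a regulator of leukocyte adhesion, was 4.34-fold lower, and Ch25h, which makes 25-hydroxycholesterol, rose 3.32-fold. The change of Ch25h was log2 0.91 on chips 1 and 5 (adjusted p = 0.177) and 2.97 on the others (adjusted p of the difference 0.00642), while Mertk changed by -0.78 and -2.45, Vegfa by -2.16 and -1.15 and Casp4 by 1.01 and 1.79. Cd69 was called higher by 1 probe (11.9-fold, with log2 2.38 on chips 1 and 5 and 5.35 on the others) but not by another (log2 -0.03). Nlrp3 (log2 0.61, adjusted p = 0.746), Hmox1 (log2 -0.02) and Il10 (log2 0.02) did not pass.

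With the set as a block, 257 genes rose and 156 fell after cyclodextrin (80 and 36 on chips 1 and 5, 499 and 437 on the other chips, 48 and 24 with the chip as a block). Scale normalization gave 45 higher and 3 lower, and without cyclodextrin replicate 1 or 5 the total was 41. The authors' table gave 472 higher and 473 lower without a set term. Its set means had already been removed, so its residual spread is then too small and these counts are too high.

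**Figure D2:**
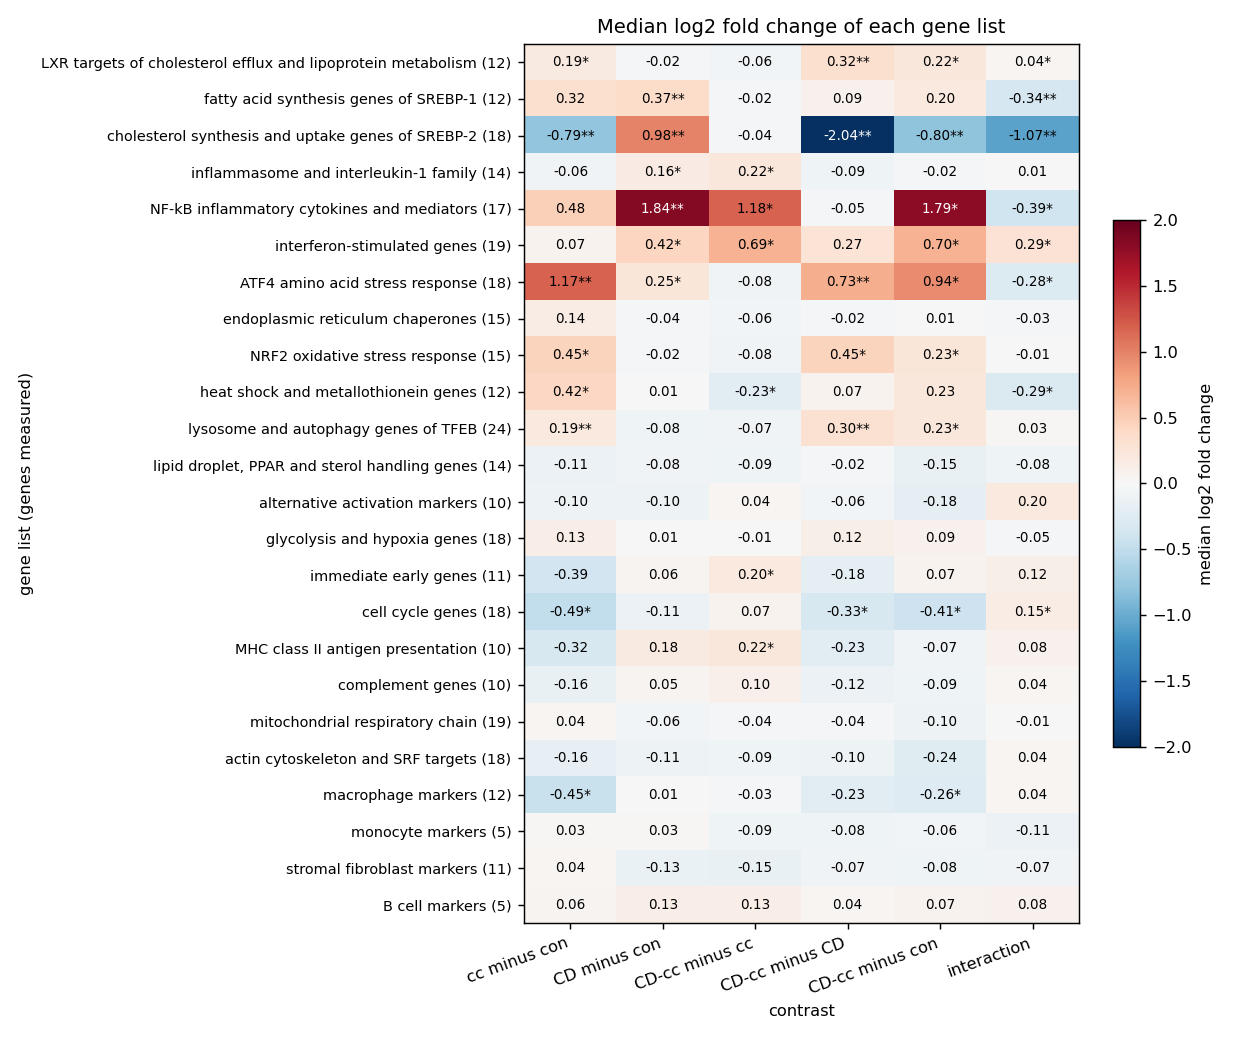
Median log2 fold change (colour and printed value) of 24 gene lists (y axis, with the number of genes measured) in the 6 contrasts (x axis), where * marks a camera adjusted p below the threshold of 0.05 and ** one that also holds with an estimated correlation. The SREBP-2 list ranges from -2.04 (crystals and cyclodextrin against cyclodextrin alone) to 0.98 (cyclodextrin against untreated), and the ATF4 list reaches 1.17 with crystals.

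Crystals then cyclodextrin against crystals alone asks what cyclodextrin did to cells already loaded, and its arrays share 1 age label. As the time the crystal-only cells stood is not given, time since loading cannot be told apart from cyclodextrin here. No gene passed in limma without a block (0 higher, 0 lower, 815 at an unadjusted p below 0.05, lowest adjusted p 0.0912). Blocking on the set, 129 genes rose and 51 fell, and the SEs of the next 4 genes come from that set-block fit. Nfkbie, an NF-kB inhibitor, rose 4.21-fold (log2 2.07 ± 0.308, set-block adjusted p = 0.00625) and Cxcl10 5.46-fold (log2 2.45 ± 0.436, set-block adjusted p = 0.0145). Tnf rose 4.89-fold (log2 2.29 ± 0.438, set-block adjusted p = 0.0160) and Vegfa was 2.43-fold lower (log2 -1.28 ± 0.181, set-block adjusted p = 0.00625). On chips 1 and 5 and on the others the change of Nfkbie was log2 1.46 and 3.00 (adjusted p of the difference 0.0060). It was 1.72 and 3.54 for Cxcl10, 1.24 and 3.87 for Tnf and -1.33 and -1.20 for Vegfa. Without the block these 4 genes had adjusted p of 0.124, 0.124, 0.248 and 0.188. Over the alternatives run on named genes the adjusted p ran from 0.00754 to 0.414 for Cxcl10, 0.00461 to 0.640 for Tnf and 1.56e-04 to 0.466 for Vegfa. The chip batches alone were not among these alternatives.

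NF-kB mediators and interferon-stimulated genes had the largest list medians. Of 17 NF-kB genes, 0 passed over all genes without the block and 6 rose with it, and 10 rose adjusted over the list alone. Their median was 1.18 (camera adjusted p = 1.98e-14, lost at adjusted p = 0.180 with an estimated correlation). It was 0.44 on chips 1 and 5 and 2.62 on the other chips, a difference with a camera adjusted p of 7.89e-33 (adjusted p = 2.83e-04 with an estimated correlation). Of 19 interferon-stimulated genes, 0 passed without the block and 11 rose with it, and 12 rose adjusted over the list alone. Examples with the block are Gbp2, a GTPase of cell defence (3.22-fold), and Rsad2, the antiviral protein viperin (3.03-fold). On chips 1 and 5 alone Gbp2 was not called (log2 0.90, adjusted p = 0.0763), against log2 2.87 on the others (adjusted p of the difference 0.00119), and Rsad2 changed by 1.19 and 2.21. The interferon list's median was 0.69 (camera adjusted p = 2.06e-14, lost at adjusted p = 0.180 with an estimated correlation), with 0.62 on chips 1 and 5 and 1.09 on the others. Within chip 1, which held both groups, the NF-kB median was 0.52 and the interferon median 0.46.

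Sterol genes did not shift as lists when cyclodextrin followed crystals. The SREBP-2 list had a median of -0.04 (camera adjusted p = 0.552) and the LXR targets one of -0.06 (camera adjusted p = 0.814). Insig1 fell with the set as a block (log2 -0.69, set-block SE 0.167, set-block adjusted p = 0.0469, adjusted p = 0.204 without it, 0.0361 to 0.868 over all alternatives). Abcg1 (log2 -0.28, adjusted p = 0.862), Abca1 (log2 0.06), Sqle (log2 0.11) and Apoe (log2 0.02) did not pass. The smaller list shifts that were called did not hold with an estimated correlation. The medians were 0.22 for inflammasome genes (camera adjusted p = 0.0175, adjusted p = 0.254 with an estimated correlation), 0.20 for immediate early genes (0.0147 and 0.180), 0.22 for MHC class II genes (0.0147 and 0.522) and -0.23 for heat shock genes (0.0175 and 0.394). Il1b (log2 1.47, adjusted p = 0.770), Nlrp3 (log2 1.04, adjusted p = 0.552) and Il10 (log2 0.39, adjusted p = 0.491) did not pass.

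Counts in this comparison depended on how the arrays were grouped. With the set block, 18 genes rose and 8 fell on chips 1 and 5, and 418 rose and 287 fell on the other chips, while the chip as a block gave 1 and 0. Without the block, leaving out replicate 1 of the cells with both treatments gave 14 genes and leaving out crystal replicate 2 gave 1.

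**Figure D3:**
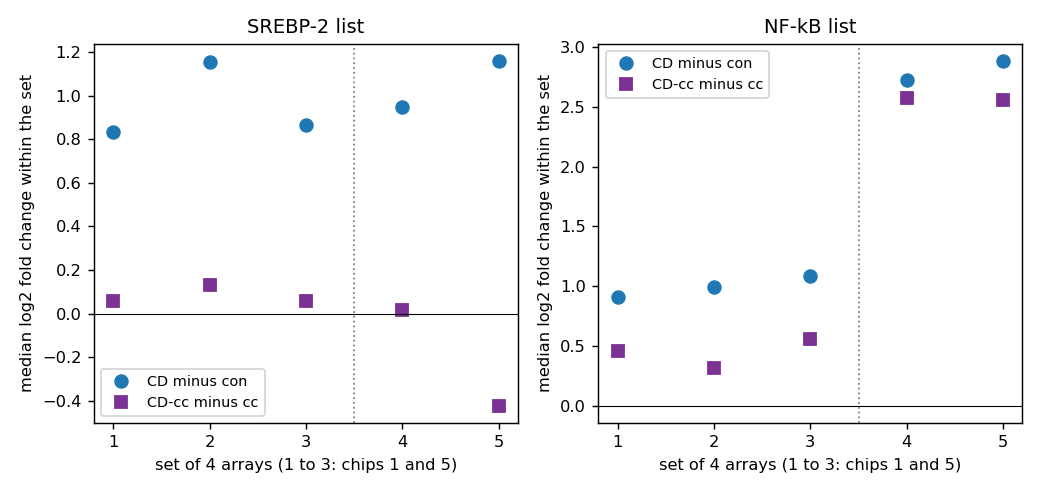
Median log2 fold change (y axis) of the SREBP-2 and NF-kB lists in each of the 5 sets of arrays (x axis), for cyclodextrin against untreated and for crystals and cyclodextrin against crystals, with a dotted line between sets 1 to 3 (chips 1 and 5) and sets 4 and 5 (other chips). After cyclodextrin alone the SREBP-2 median lay between 0.83 and 1.16 in all 5 sets, while the NF-kB median was 0.90 to 1.08 in sets 1 to 3 and 2.73 to 2.88 in sets 4 and 5.

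Crystals then cyclodextrin against cyclodextrin alone asks what crystals did in cells that both received cyclodextrin, again with 1 age label. Abcg1 was 35.9-fold higher in cells that had taken crystals (log2 5.17 ± 0.235, adjusted p = 2.28e-11). Stard4 was 12.6-fold lower (log2 -3.65 ± 0.231, adjusted p = 2.64e-09), Cyp51 11.3-fold lower (log2 -3.50 ± 0.184, adjusted p = 1.71e-10) and Insig1 7.62-fold lower. Eepd1, an LXR-responsive gene of cholesterol efflux, rose 9.76-fold (log2 3.29 ± 0.240, adjusted p = 1.68e-08). Abcg1, Stard4, Cyp51 and Insig1 each moved one way in 5 of 5 sets. In all, 457 genes rose and 465 fell, 122 and 88 of them by at least 2-fold.

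Of the 18 SREBP-2 genes, 17 were lower and 0 higher, with a median of -2.04 (camera adjusted p = 2.34e-39, and adjusted p = 2.54e-05 with an estimated correlation). The medians were -1.93 on chips 1 and 5, -2.31 on the others and -2.17 within chip 6, which held a single array of each group, from different sets. LXR targets gave 3 of 12 higher, namely Abcg1, Mertk (3.09-fold) and Abca1 (at least 1.56-fold). Their median was 0.32 (camera adjusted p = 2.78e-04, and adjusted p = 0.0310 with an estimated correlation). Of 12 SREBP-1 genes, 4 fell, led by Elovl6 (4.48-fold lower), and 0 rose. That list's median of 0.09 and mean of -0.14 differ in sign, its test pointed down, and it was not called (camera adjusted p = 0.368). Of 18 ATF4 genes, 10 rose and 0 fell (15 adjusted over the list alone), among them Trib3 (5.66-fold) and Ddit3 (4.12-fold). Their median was 0.73 (camera adjusted p = 1.90e-12, and adjusted p = 0.0499 with an estimated correlation).

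Other lists shifted in the direction seen with crystals alone. Of 24 lysosome genes, 6 rose (7 adjusted over the list alone), with a median of 0.30 (camera adjusted p = 4.22e-05, and adjusted p = 0.0258 with an estimated correlation). Of 15 NRF2 genes, 5 rose (8 adjusted over the list alone), such as Gsta3 (5.91-fold, with log2 3.20 on chips 1 and 5 and 1.61 on the others) and Hmox1 (3.14-fold), with a median of 0.45 (camera adjusted p = 1.81e-06, lost at adjusted p = 0.129 with an estimated correlation). Of 18 cell cycle genes, 2 fell, Cdk1 and Birc5, with a median of -0.33 (camera adjusted p = 0.0137, lost at adjusted p = 0.492 with an estimated correlation). Ch25h was 3.64-fold lower, Cx3cr1 3.60-fold lower and the cytokine Il18 2.52-fold lower, while Vegfa rose 2.49-fold. Kit was at least 9.81-fold higher, as no array of cyclodextrin alone detected it. Tnf (log2 0.43, adjusted p = 0.783), Il1b (log2 -2.62, adjusted p = 0.0918) and Srebf1 (log2 0.64, adjusted p = 0.0508) did not pass without a block. With the set as a block 848 genes rose and 1010 fell (884 and 1089 on chips 1 and 5, 199 and 147 on the others), and with the chip as a block 127 and 96. Without cyclodextrin replicate 2 the total was 599.

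Crystals then cyclodextrin against untreated cells gives the joint effect of both treatments, with the age label again confounded. Acod1 rose 53.0-fold (log2 5.73 ± 0.686, adjusted p = 2.69e-05), Clec4e, a receptor for microbial glycolipids and dying cells, 17.5-fold (log2 4.13 ± 0.560, adjusted p = 7.13e-05) and Tnf 9.95-fold (adjusted p = 0.00159). Cytip was 12.2-fold lower (log2 -3.61 ± 0.473, adjusted p = 5.04e-05). Each of Acod1, Tnf and Cytip moved one way in 5 of 5 sets. On chips 1 and 5 and on the others the rise was log2 5.03 and 6.78 for Acod1, 3.56 and 5.00 for Clec4e and 2.45 and 4.62 for Tnf. In all, 908 genes rose and 1117 fell, 251 and 200 of them by at least 2-fold.

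Of 17 NF-kB genes, 13 rose and 0 fell (14 adjusted over the list alone), such as Cxcl2 (11.7-fold, with log2 2.39 on chips 1 and 5 and 5.27 on the others) and Ccl2 (2.40-fold), both chemokines. Their median was 1.79 (camera adjusted p = 7.53e-09, lost at adjusted p = 0.276 with an estimated correlation), with 1.06 on chips 1 and 5 and 2.97 on the others (camera adjusted p of the difference 1.51e-23). Of 19 interferon-stimulated genes 7 rose (9 adjusted over the list alone), with a median of 0.70 (camera adjusted p = 2.77e-04, lost at adjusted p = 0.478 with an estimated correlation). Of 18 ATF4 genes 15 rose, with a median of 0.94 (camera adjusted p = 7.18e-13, lost at adjusted p = 0.0894 with an estimated correlation). Of 18 SREBP-2 genes 15 fell and 0 rose (17 adjusted over the list alone), with a median of -0.80 (camera adjusted p = 1.67e-13, and adjusted p = 0.0103 with an estimated correlation). Abcg1 was 6.52-fold higher and Nr1h3 2.27-fold higher (adjusted p = 0.00263). Interleukin-1 alpha mRNA, Il1a, was at least 3.37-fold higher (log2 1.18 on chips 1 and 5 and 3.36 on the others).

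Of the remaining lists called between these groups, none held with an estimated correlation. The medians were 0.23 for NRF2 genes (6 of 15 higher, camera adjusted p = 2.77e-04, adjusted p = 0.280 with an estimated correlation), 0.23 for lysosome genes (6 of 24 higher and 1 lower, 0.00476 and 0.155) and 0.22 for LXR targets (3 of 12 higher, 0.0278 and 0.266). The LXR median was 0.46 within chip 1 and -0.14 within chip 4, and the other 8 called lists kept their direction on both chips. Chip 1 held a single untreated array, and chip 4 a single array of each group, from different sets. The medians of the falling lists were -0.41 for cell cycle genes (5 of 18 lower, 0.00165 and 0.280) and -0.26 for macrophage markers (3 of 12 lower, 0.0315 and 0.478). Il10 fell (log2 -0.95, adjusted p = 3.62e-04). With the set as a block 1371 genes rose and 1818 fell (1109 and 1408 on chips 1 and 5, 820 and 873 on the others), and with the chip as a block 524 and 625.

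The interaction asks whether cyclodextrin acted differently on cells with and without crystals, and includes the untreated cells and their age label. Among 4 genes called, the sterol genes Mvd (log2 -2.21 ± 0.284, adjusted p = 9.74e-04), Insig1 (log2 -1.79 ± 0.265, adjusted p = 0.00513) and Aacs (log2 -1.43 ± 0.164, adjusted p = 3.23e-04) had a lower response to cyclodextrin with crystals present. Aacs feeds ketone bodies into sterol synthesis. Abcg1 had the positive value (log2 2.19 ± 0.332, adjusted p = 0.00554), from a lower level after cyclodextrin without crystals that did not appear with them. All 4 kept their direction in 5 of 5 sets. With the set as a block 2 genes were higher and 12 lower, among them Stard4 (log2 -1.53), Fdps (log2 -1.46) and Sqle (log2 -1.18), all sterol genes. Counts were 2 and 7 on chips 1 and 5, 0 and 8 on the others, and 1 and 3 with the chip as a block, and the total was 8 without crystal replicate 1 or replicate 5 of both treatments.

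The SREBP-2 list gave the largest median of the interaction, -1.07 (camera adjusted p = 1.59e-46, and adjusted p = 8.44e-06 with an estimated correlation), with 2 of 18 lower over all genes and 15 lower adjusted over the list alone. It was -0.81 on chips 1 and 5 and -1.44 on the others. SREBP-1 genes had a median of -0.34 (camera adjusted p = 1.76e-07, and adjusted p = 2.34e-04 with an estimated correlation) with 0 of 12 past the test. The other called medians did not hold with an estimated correlation. They were -0.39 for NF-kB genes (camera adjusted p = 0.00773, adjusted p = 0.757 with an estimated correlation), 0.29 for interferon-stimulated genes (0.0174 and 0.759), -0.28 for ATF4 genes (3.12e-04 and 0.453), -0.29 for heat shock genes (5.83e-04 and 0.194), 0.15 for cell cycle genes (3.67e-04 and 0.248) and 0.04 for LXR targets (0.0365 and 0.248).

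Across 10018 genes, which are not independent replicates, the effects of cyclodextrin with and without crystals correlated at r = 0.657 from 4 different groups of arrays. That r was 0.318 on chips 1 and 5 and 0.787 on the others, and with the chip as a block it was 0.398. Within sets 1 to 3 it was 0.00272, 0.372 and -0.174, and within sets 4 and 5 it was 0.595 and 0.684, so the correlation did not hold in every set. With the set as a block, 71 genes rose and 13 fell in both, where independence would give 3.31 and 0.794, and 1 gene went opposite ways. On chips 1 and 5 alone 8 rose and 2 fell in both (0.144 and 0.0287 under independence). On the other chips 311 rose and 199 fell in both (20.8 and 12.5 under independence), and 2 went opposite ways. The effects of crystals with and without cyclodextrin correlated at r = 0.857, with 397 genes higher in both, 366 lower in both (38.8 and 41.7 under independence) and 0 in opposite directions. Within single sets that r lay between 0.410 and 0.733.

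**Figure D4:**
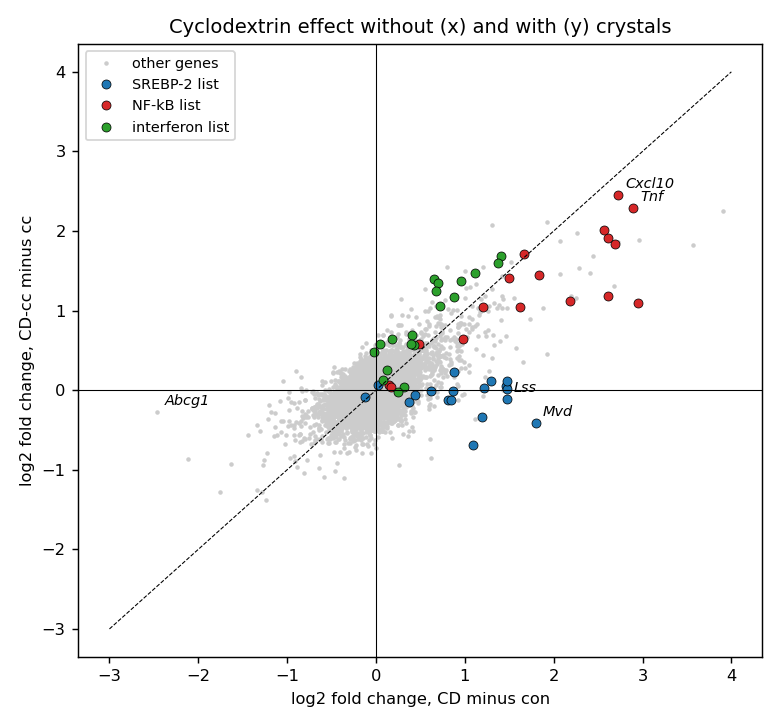
Log2 fold change of each of 10018 genes after cyclodextrin without crystals (x axis, cyclodextrin minus untreated) and with them (y axis, crystals and cyclodextrin minus crystals), grey for other genes, blue for the SREBP-2 list, red for NF-kB and green for interferon, with a dashed line of equal effects. NF-kB genes such as Tnf lie high on both axes (2.89 and 2.29), while SREBP-2 genes such as Mvd are raised along x (1.80) but not along y.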

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

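The tests of explanations in this part were all chosen after the results they concern had been seen. Effects were compared between chips 1 and 5 (sets 1 to 3, high Xist) and chips 2, 3, 4 and 6 (sets 4 and 5, high Eif2s3y) with an interaction term in limma and the set as a block. The effect of cyclodextrin in crystal-loaded cells differed for 228 genes (155 more positive and 73 more negative on chips 2, 3, 4 and 6), and that of cyclodextrin against untreated cells for 205. The numbers were 121 for crystals against untreated cells, 34 for crystals among cyclodextrin-treated cells and 294 for both treatments against untreated cells. For the interaction of both treatments limma called 0 genes, with 348 at an unadjusted p below 0.05. For cyclodextrin averaged over both kinds of cells, 569 genes differed. They include the neutrophil chemokines Cxcl1 (log2 0.51 on chips 1 and 5 and 4.95 on the others, adjusted p of the difference 4.09e-07) and Cxcl2 (0.36 and 4.52), and Il1b (0.19 and 4.56). For crystals 372 genes differed, among them the cystine importer Slc7a11 (3.76 on chips 1 and 5 and 1.37 on the others) and Chac1 (3.01 and 1.41).

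A first pattern is that the NF-kB list rose after cyclodextrin by a median of 0.90 on chips 1 and 5 and 2.79 on the others. The crystal response on chips 1 and 5 was 1.9 times that on the other chips, which goes against compressed signal there. Its genes were picked from these same arrays, with most sets on chips 1 and 5, so the choice raises that ratio and the evidence is weak. Wrongly labelled cyclodextrin arrays on chips 1 and 5 are argued against, since the SREBP-2 list rose there in each of the 3 sets (lowest median 0.831). A higher starting level on chips 1 and 5 is argued against too, since cyclodextrin-treated cells of chips 2, 3, 4 and 6 lay above those of chips 1 and 5 by a median of 1.86, although for Il1b alone most of the gap lay in untreated cells (9.23 on chips 1 and 5 and 5.41 on the others). The sex of the animals cannot be told apart from the chip batch, because 0 batches held arrays of both inferred sexes. A difference between sexes may thus lie behind the pattern, and so may one between cultures or days of the sets.

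A second pattern is that SREBP-2 genes rose after cyclodextrin without crystals but not with them. Signal near background in loaded cells is argued against, since the 14 members detected on all 20 arrays had a median interaction of -1.27, and so is a single set or batch, since the highest of the 5 set medians was -0.532. The older age label of the untreated cells cannot be told apart from the treatment here, because 0 untreated arrays carry the label of the cyclodextrin group. Nor can the time that untreated and crystal-only cells stood, which is not given. Sterol from crystals that outlasts the cyclodextrin is a hypothesis that stays open, as sterol was not measured. The SREBP-2 median of -2.04 in loaded against unloaded cells, both given cyclodextrin and with 1 age label, largely restates the pattern and gives it no separate support.

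The last pattern is that crystal-loaded cells differed from untreated cells in 1750 genes although the age labels differ too. Age as the whole cause is argued against, since 99 percent of those genes had the same sign between loaded and unloaded cells among cyclodextrin-treated cells, whose arrays share 1 age label. A part of the difference in single genes may still come from age, which was not tested.

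Single arrays stood apart from the other 4 of their group in 26 of 700 combinations of gene and group tested with Dixon's ratio (critical value 0.71), where chance flags about 1 in 20 groups, or 35 here. The ratio is the gap to the nearest array over the range of the group. In untreated replicate 4 it was 0.748 for Chac1, 0.784 for Fcgr1, 0.825 for Thbs1, 0.714 for Cd14 and 0.816 for H2-DMa, and in untreated replicate 3 it was 0.755 for C1qa. With crystals it was 0.715 for C1qa (replicate 3), 0.77 for C4b and 0.714 for Stab1 (both replicate 5), 0.839 for Mylip and 0.79 for Uvrag (both replicate 1) and 0.841 for Fos (replicate 2). With cyclodextrin it was 0.851 for Ly6c1 (replicate 1), 0.736 for Egln3 (replicate 2), 0.742 for Hsp90aa1 (replicate 4) and 0.758 for C3ar1 (replicate 5). With both treatments, replicate 4 gave 0.734 for Pdgfrb, 0.888 for Notch4, 0.73 for Atp6v0d1, 0.778 for Fads1 and 0.753 for Aacs. Replicate 2 of that group gave 0.75 for Itgam, 0.731 for Ndrg1 and 0.733 for Rrm2, replicate 1 gave 0.762 for Zfp36 and replicate 5 gave 0.718 for Fdps.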

How the results depend on the processing

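The set block, the analyses of chips 1 and 5 or chips 2, 3, 4 and 6 alone and the one without the 3 arrays of lowest signal were chosen after seeing the data, and all other tests here before. No called list was called in the opposite direction under an alternative. The LXR median of the interaction, positive without a block, was -0.02 with the chip as a fixed block, where the list was not called. No named gene changed sign in a comparison where it was called, under the alternatives run on named genes. These left out the chip batches alone, the stricter detection filter and the authors' table with the set block. They also left out the fit without the 3 arrays of lowest signal. Between the chip batches some named genes that were not called without a block changed sign. Examples are Il1b after crystals (log2 -3.45 on chips 1 and 5, 0.97 on the others) and Atf3 after cyclodextrin (0.78 and -0.45). Il1a did so for both treatments against crystals (-0.36 and 2.19). The balance of genes higher and lower also changed sides, as for crystals against untreated cells (851 and 899, but 423 and 230 with scale normalization and 257 and 172 on chips 2, 3, 4 and 6) and both against cyclodextrin (457 and 465, but 127 and 96 with the chip block). Of the named genes' values under single alternatives, 8413 kept their side of the threshold, 342 lost it and 111 gained it, and of the values of lists called without a block 1067 kept it and 131 lost it. Of the overlaps between comparisons 8 values moved and 8 did not. Lists not called without a block could gain a call. With the chip as a fixed block these were NF-kB (camera adjusted p = 0.00550) and glycolysis genes (0.0487) for crystals against untreated cells, ATF4 (0.0116), NRF2 (0.0266) and cell cycle genes (0.0381) for both treatments against crystals, and macrophage markers (0.0107) for both against cyclodextrin. With the set block they were NF-kB (0.0297), glycolysis (0.0418) and MHC class II genes (0.0368) for crystals against untreated cells and macrophage markers (0.0279) for both against cyclodextrin. Below, called genes are given in the order crystals and cyclodextrin against crystals (0 as reported), cyclodextrin against untreated (113), crystals against untreated (1750), both against cyclodextrin (922), both against untreated (2025) and the interaction (4), where they moved by over 1.5 times. Except where named, the cause was not tested.

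Scale normalization gave 1, 48, 653, 266, 821 and 0. The authors' table gave 610, 945, 3669, 2820, 4065 and 30. Its set means had already been removed, so its residual spread without a set term is too small by construction, and with the set block it gave 157, 407, 2873, 1970, 3213 and 16. The set block on the bead signals gave 180, 413, 2772, 1858, 3189 and 14. The chip as a fixed block gave 1 for the first, 72 for the second, 223 for the fourth and 1149 for the fifth. Chips 1 and 5 with the set block gave 26 for the first, 2828 for the third, 1973 for the fourth and 9 for the interaction, and the other chips gave 705, 936, 429, 346 for the first 4 and 8 for the interaction. A minimum change of 2-fold gave 58 for the second, 372 for the third, 210 for the fourth and 451 for the fifth, fewer by construction. Only the groups of the contrast gave 53 for the second and 596 for the fourth. Without the 3 arrays of lowest signal the second gave 46. The interaction gave 11 without background correction and 8 with array weights.

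With an estimated correlation camera called 0 of 6 lists for the first comparison, 3 of 6 for the second, 3 of 8 for the third, 1 of 9 for the fifth and 2 of 8 for the interaction, while fry called 0 for the first and 2 for the interaction. Leaving out 1 array gave 0 to 14 genes for the first comparison (14 without replicate 1 of both treatments), 41 to 119 for the second, 1230 to 1694 for the third, 599 to 1108 for the fourth, 1557 to 1937 for the fifth and 4 to 8 for the interaction. In the second it gave 41 without cyclodextrin replicate 1 or 5, 58 without untreated replicate 3 or 5, 64 without untreated replicate 4 and 67 without untreated replicate 2. Called lists ranged over 3 to 7, 4 to 8, 8 to 10, 6 to 8, 8 to 9 and 5 to 9. Replicate numbers did not pair the samples (r of deviations -0.563 to 0.654, with 8 of 30 pairs over 0.1, against 27 of 30 for the sets), and as a block they gave 1, 92, 1553, 823, 1822 and 4. Signal over background limits dim genes, whose fold changes the offset of 16 shrinks.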

Other observations

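The genes of the first paragraphs follow the rule set in advance, and of the tests below the one on sets was chosen after its result had been seen, while the regroupings of arrays were planned, except the exchanges within sets, which were added later. Among the genes with the largest rise with crystals was Plpp3, a phosphatase of lysophospholipids, which was 10.4-fold higher against untreated cells (log2 3.37 ± 0.719, adjusted p = 0.00287). Its other probe gave log2 0.63. Gprc5b, an orphan receptor, was 7.79-fold higher (log2 2.96, other probe 1.06) and Spsb4 6.09-fold higher (log2 2.61, other probe 0.79) with crystals among cyclodextrin-treated cells. In the list of lipid droplet and sterol handling genes, which was not called as a list, Fabp5, a fatty acid carrier, rose 2.86-fold with crystals against untreated cells, while Cyp27a1, which makes 27-hydroxycholesterol, fell (log2 -1.03, adjusted p = 0.0214).

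Cyclodextrin without crystals also raised Mycl, a MYC family factor, 7.78-fold (log2 2.96 ± 0.470, adjusted p = 0.00345) and Fpr2, a receptor for formyl peptides, 6.61-fold, by log2 1.08 on chips 1 and 5 and 5.19 on the others. Notch4 was 2.47-fold lower and the growth factor Hgf 2.42-fold lower. With both treatments against untreated cells, the anion transporter Slco2b1 was 6.31-fold lower.

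Within chip batches, arrays of different groups that shared a set deviated alike from their group means (median r 0.33, lowest -0.251). Where they did not share a set the median r was -0.231. Centring on so few arrays per group ties that value to the first by construction. The difference of 0.561 is therefore inflated and gives no separate support. The median of 0.33 argues against the chip batch alone as the cause. The sets may be shared cultures, which the labels do not state.

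To count how often other regroupings of the arrays give as many genes, 100 regroupings per comparison, the real one included, were fitted in limma. For both treatments against crystals the real count of 0 is reached by any regrouping (100 of 100, highest other 48), so this says nothing about chance. With the set block, 1 of the 16 exchanges of these groups within sets, the real one, reached its 180 genes (highest other 0), but 16 are too few for a share below 0.05. For cyclodextrin against untreated cells 2 of 100 reached the real 113. The other was 1154, many times the real count, in a regrouping that put 1 array of chips 1 and 5 in one part and the rest in the other, so it followed the chip batch and points to that structure of the arrays. Within the batches, with the set block, 80 genes rose and 36 fell on chips 1 and 5, and 499 rose and 437 fell on the others. The next highest was 11. For crystals against untreated cells 1 of 100 reached 1750 (highest other 29), and for both against untreated cells 1 of 100 reached 2025 (highest other 1). For both against cyclodextrin 1 of 100 reached 922, while the highest other, 762, again followed the chip batch. For the interaction 1 of 100 reached 4 (highest other 2). Those regroupings mixed all 4 groups, so the effects of crystals and of cyclodextrin entered the spread, and they cannot test the interaction. For the comparisons of a pair of groups after the first, the regroupings ignored the sets, so chance is argued against only where the sets are ignored. Exchanges within sets are too few to test a comparison of a pair of groups. For the interaction, which uses every group, they were not run.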
